A study of Homo sapiens with 12 samples.

How the data were processed

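Gene expression was measured in 12 samples of HepG2 cells on Affymetrix HG-U133 Plus 2 arrays, with 4000000 cells plated per plate and RNA isolated 24 hours after adenoviral infection. The deposited values are signal intensity per probe set on a linear scale, made by the authors with the MAS5 algorithm, for which no version is stated. Background settings, the scaling target and detection calls are not given in the sources used here. The deposited intensity was already scaled: the mean of each array's values between the 2nd and 98th percentile lay between 499.5 and 499.9. The highest signal per array lay between 32868 and 47907. For arrays no read depth applies, and the 3 arrays per group limit the precision; the median standard error of a log2 change was 0.139.

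Of 54675 probe sets, 62 controls were left out. The platform annotation gave 1 gene symbol for 41097 probe sets, several for 1801 and none for 11721, and 0 symbols were changed by a human gene table used for names. Signals were taken to log2(signal + 14), 14 being the 10th percentile of all values, so fold changes of dim genes are understated. Probe sets with a mean signal of at least 137, the median, were kept (27307). Of these, 22714 had 1 gene symbol, and each gene was represented by its brightest probe set, which left 12658 genes. The 4593 kept probe sets without a single listed gene were tested apart.

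Differences were tested with limma 3.58.1 in R 4.3.3: 1 linear model over all 12 arrays with 1 coefficient per group, moderated with eBayes (trend), 2-sided, and Benjamini-Hochberg adjustment within each of the 6 comparisons. A gene was called at an adjusted p under 0.05. The p-values rest on a spread pooled over the 4 groups with 8 residual degrees of freedom. Median log2 changes over all genes stayed under 0.1 in size in each comparison, with and without quantile normalization and median centring.

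Before the data were examined, 24 gene lists were written: oxidative phosphorylation, tricarboxylic acid cycle, fatty acid oxidation, PPAR alpha targets and peroxisome, gluconeogenesis, mitochondrial transcription and import, mitochondrial ribosome, antioxidant and uncoupling, apolipoproteins and bile acids, hepatocyte identity, nuclear receptors and coregulators, cholesterol synthesis, lipogenesis, glycolysis, heme synthesis, xenobiotic metabolism, interferon response, NF-kappaB and acute phase, p53 targets, cell cycle, ER stress and ATF4, cytosolic ribosome, muscle and brown fat, and markers of other cell types. They were tested with camera at a preset correlation of 0.01, adjusted over all 144 tests of lists and comparisons. Of the 57 calls, 7 held with an estimated correlation and 57 with fry. Fry tests whether a list's genes move one way on balance and compares them with no other genes. It called 13 to 21 of the 24 lists in each comparison, so its 57 adds little support.

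The rule for named genes was also fixed before the data were examined. Per comparison it names the 8 largest increases and 6 largest decreases among called genes whose groups do not overlap, which for 3 arrays against 3 also happens by chance in 10% of unchanged genes, the 3 called members of each list with the largest absolute log2 change, and fixed genes linked to PGC-1 whether called or not, 11 of which had probe sets. Uncharacterised symbols (LOC, LINC and open reading frames) were passed over. This gave 505 results. The text names a part of them, chosen by the order of the rule and not by how they fared under other settings: all 14 largest changes, the fixed genes, and from each called list the first 1 or more members in order of absolute change. All 505 were recomputed under the alternatives.

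The comparisons were chosen from the group labels before the data were examined. The alternatives changed 1 choice at a time: the pseudocount (none, with values floored at 1, or 39, the 25th percentile), the filter (none, or a mean signal of 357, the 70th percentile), quantile normalization, median centring, the mean of all probe sets of a gene, leaving out probe sets ending in _s_at and _x_at, which can match several transcripts, a replicate block, only the 2 compared groups in the fit, eBayes without the trend, array weights, a minimum of 2-fold, and each array left out in turn. A replicate block was not used in the main model because replicate numbers did not pair the arrays: after removing group means, 18 pairs with the same number correlated at -0.0852 to 0.0686. Overlaps between called genes were compared with independent lists of the same sizes and with 50 simulations of arrays without change, because comparisons with BGAL share arrays.

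The model was tested on simulated data with 200 changed genes among 12658: it recovered 42% of genes changed by log2 0.5, 75% by log2 1 and 98% by log2 2, and 7 of 152 calls were false. A shifted list was found in 20 of 20 draws and an unshifted one in 2 of 20. In the measured data 16.1% to 47.2% of genes were called per comparison, so the recovery rates do not carry over directly. Genes were simulated as independent, so the draws do not test lists of correlated genes. The count of genes whose probe sets move in opposite directions was tested on simulated data too and found 48 of 50 planted genes, with 0 in data without change. Positions of probes on transcripts were not used here.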

Results

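Messenger RNA was measured in HepG2 cells, a human hepatocellular carcinoma line, 24 hours after infection with adenovirus at a multiplicity of infection of 10 to 30. The 4 groups received virus coding for beta-galactosidase (BGAL, the control), wild-type PGC-1 (wt) or the PGC-1 variants 2x9 and L2L3. PGC-1 alpha is a transcriptional coactivator of genes of energy metabolism, and ERR alpha, encoded by ESRRA, is one of the nuclear receptors it acts through. Each group held 3 arrays from 3 biological replicates, 12 arrays in all, and their number limits the precision of every value. Every array carried 54675 probe sets, and 12658 genes were tested.

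The median signal per array lay between 126 and 152, and the mean signal between the 2nd and 98th percentile between 499.5 and 499.9. Arrays of the same group correlated at r = 0.973 to 0.978 across the tested genes, which are not independent replicates. BGAL and L2L3 arrays correlated at 0.962 to 0.968, wt and 2x9 arrays at 0.947 to 0.953, wt and BGAL arrays at 0.916 to 0.927, and 2x9 and BGAL arrays at 0.896 to 0.903. The ratio of 3' to 5' GAPDH signal, a measure of RNA integrity, averaged 0.875 ± 0.0226 in BGAL, 0.848 ± 0.0246 in wt, 0.839 ± 0.0288 in 2x9 and 0.860 ± 0.00442 in L2L3 (SD, n = 3). Signals are given below as mean ± SD (n = 3 arrays), and log2 changes, on the scale of log2(signal + 14), as estimate ± SE. For genes near background in 1 group, the size and order of log2 changes depend on the 14 added: APOA4 in wt against L2L3 was at 8.32 with none and 7.46 with 39, and OGDHL in wt against BGAL at 7.08 and 5.10.

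**Figure D1:**
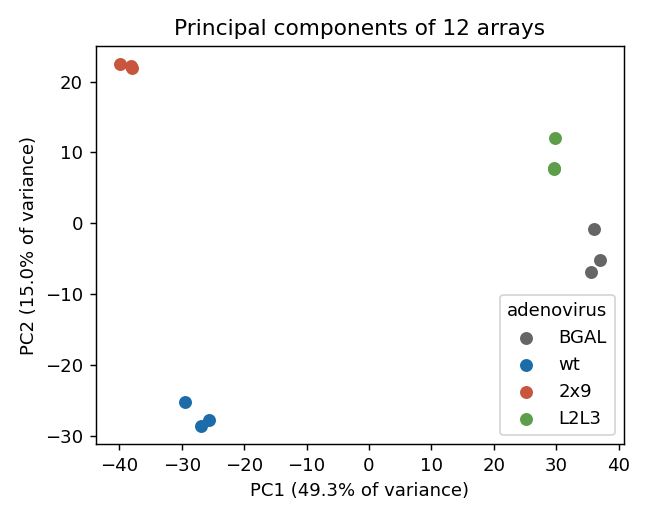
Principal components of the 12 arrays, 1 point per array, coloured by adenovirus; PC1 (x axis) holds 49.3% of the variance, and PC2 is on the y axis. BGAL and L2L3 arrays lie on the positive side of PC1, and wt and 2x9 arrays on the negative side, apart from each other on PC2.

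The comparison of wt with BGAL asks what wild-type PGC-1 changes in these cells. Oxidative phosphorylation and fatty acid oxidation genes were higher with wt and cell cycle genes lower, as counted below. APOA4, an apolipoprotein, rose from a signal of 119 ± 78.6 in BGAL to 18738 ± 1749.6 in wt (log2 7.31 ± 0.48, adjusted p = 2.04e-08). OGDHL, related to the oxoglutarate dehydrogenase subunit OGDH, rose from 13.2 ± 3.12 to 1763 ± 312, and PCK1, the gluconeogenic phosphoenolpyruvate carboxykinase, from 36.5 ± 22.9 to 1437 ± 218. The other genes among the 8 largest increases were GAL3ST1, a sulfotransferase (log2 5.92 ± 0.31), ITGB2, an integrin subunit (5.77 ± 0.26), the transcription factor CREB3L3 (4.93 ± 0.40), the small GTPase RRAGD (4.65 ± 0.24) and CYP17A1, a steroid hydroxylase (4.44 ± 0.25). IGFBP1, a binding protein of insulin-like growth factors, fell from 9698 ± 910.1 to 811 ± 98.7 (log2 -3.56 ± 0.0891, adjusted p = 1.72e-12). The EGF family ligand EREG changed by log2 -3.36 ± 0.38, the transcription factor PAX6 by -3.33 ± 0.45, TNS4 by -3.11 ± 0.32, the protease inhibitor TFPI2 by -2.91 ± 0.44 and RGS10 by -2.83 ± 0.37.

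Genes fixed in advance for their links to PGC-1 rose with wt. ESRRA rose from 1103 ± 178 to 4272 ± 408 (log2 1.95 ± 0.11), CPT1A, which admits fatty acids to mitochondria, from 561 ± 21.6 to 4579 ± 262 (log2 3.00 ± 0.11), and G6PC1, the catalytic subunit of glucose-6-phosphatase, from 368 ± 96.3 to 5669 ± 959.9 (log2 3.91 ± 0.16). A dimmer probe set of G6PC1 rose from 3.73 ± 0.862 to 6708 ± 1176; the first is under the 14 added to every signal, so no log2 change is given for it. The log2 change was 1.76 ± 0.0992 for NR0B2, a repressive nuclear receptor, 1.33 ± 0.0862 for ACADM, 1.07 ± 0.0892 for ALAS1 and 0.77 ± 0.0575 for CYCS, cytochrome c. IDH3A, a subunit of isocitrate dehydrogenase, rose by log2 2.42 ± 0.0761 through its brightest probe set; without probe sets ending in _s_at and _x_at, its dim remaining probe set gave 0.50 (adjusted p = 0.402). PPARGC1A, the gene of PGC-1 alpha, was below the signal filter: 1 of its 2 probe sets read 134 ± 17.8 in BGAL, 86.9 ± 26.2 in wt, 50.9 ± 17.5 in 2x9 and 76.1 ± 35.9 in L2L3, and the other 69.4 ± 70.4, 76.0 ± 51.0, 89.4 ± 31.4 and 32.7 ± 5.74. Whether these probes lie within the viral constructs is not given in the sources used here, so whether they measure the expression of the constructs is not known. PDK4 was also below the filter.

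Among the gene lists fixed before the data were examined, oxidative phosphorylation had the lowest camera adjusted p with wt, though not the largest median change. In it 64 of 68 measured members rose and 0 fell (65 and 0 adjusted over the list alone), with a median log2 change of 0.80. For oxidative phosphorylation camera gave adjusted p = 3.58e-33, and adjusted p = 0.022 with an estimated correlation. NDUFA1 (1.68 ± 0.16) and NDUFA8 (1.63 ± 0.0642), both of complex I, had its largest changes. In fatty acid oxidation 18 of 21 measured members rose and 0 fell (18 and 0 adjusted over the list alone), with a median log2 change of 1.03. For fatty acid oxidation camera gave adjusted p = 2.39e-12, and adjusted p = 0.0263 with an estimated correlation. Its largest change was that of SLC25A20, the carnitine-acylcarnitine carrier, from 485 ± 27.5 to 4717 ± 231. In the tricarboxylic acid cycle 17 of 19 measured members rose and 0 fell (17 and 1 adjusted over the list alone), with a median log2 change of 0.88, IDH3A and the pyruvate carrier MPC1 (2.02 ± 0.11) first. For the tricarboxylic acid cycle camera gave adjusted p = 1.56e-12, and adjusted p = 0.0521 with an estimated correlation. Of the cell cycle genes 1 of 44 measured members rose and 37 fell (1 and 37 adjusted over the list alone), with a median log2 change of -0.68. For cell cycle genes camera gave adjusted p = 6.65e-13, and adjusted p = 0.022 with an estimated correlation. CCNE2, cyclin E2, went from 1477 ± 175 to 417 ± 29.6, and MCM6, of the replicative helicase, changed by log2 -1.35 ± 0.10.

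Of apolipoprotein and bile acid genes 16 of 23 measured members rose and 1 fell (16 and 1 adjusted over the list alone), with a median log2 change of 0.82. For apolipoproteins and bile acids camera gave adjusted p = 1.87e-06, and adjusted p = 0.052 with an estimated correlation. After APOA4 came CYP7A1, the rate-limiting enzyme of bile acid synthesis, which rose from 32.8 ± 13.5 to 783 ± 137. Mitochondrial ribosome genes followed: 35 of 76 measured members rose and 4 fell (39 and 6 adjusted over the list alone), with a median log2 change of 0.18, MRPL34 (1.75 ± 0.0692) first. For mitochondrial ribosome genes camera gave adjusted p = 4.05e-07, and adjusted p = 0.211 with an estimated correlation. In cholesterol synthesis 7 of 15 measured members rose and 0 fell (7 and 0 adjusted over the list alone), with a median log2 change of 0.16, NSDHL (0.86 ± 0.082) first. For cholesterol synthesis camera gave adjusted p = 0.00947, and adjusted p = 0.116 with an estimated correlation. In xenobiotic metabolism 7 of 12 measured members rose and 0 fell (7 and 0 adjusted over the list alone), with a median log2 change of 0.40, CYP1A1 (1.75 ± 0.15) first. For xenobiotic metabolism camera gave adjusted p = 0.0108, and adjusted p = 0.0956 with an estimated correlation. Of antioxidant and uncoupling genes 8 of 19 measured members rose and 2 fell (8 and 2 adjusted over the list alone), with a median log2 change of 0.23, with the ADP/ATP carrier SLC25A4 (2.30 ± 0.0717) first. For antioxidant and uncoupling genes camera gave adjusted p = 0.0106, and adjusted p = 0.114 with an estimated correlation. Mitochondrial transcription and import genes moved both ways: 16 of 29 measured members rose and 6 fell (16 and 6 adjusted over the list alone), with a median log2 change of 0.25, the import pore gene TOMM40 (1.21 ± 0.0706) first. For mitochondrial transcription and import camera gave adjusted p = 0.0304, and adjusted p = 0.237 with an estimated correlation, and the call was lost with the filter at the 70th percentile (0.0544) and without probe sets ending in _s_at and _x_at (0.159). In gluconeogenesis 5 of 11 measured members rose and 2 fell (5 and 2 adjusted over the list alone), with a median log2 change of 0.38, PCK1 and G6PC1 first. For gluconeogenesis camera gave adjusted p = 0.0354, and adjusted p = 0.132 with an estimated correlation. Its call was lost without wt replicate 2 (adjusted p = 0.0577), with the filter at the 70th percentile (0.0733) and with only the 2 groups in the fit (0.0675).

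The other 13 lists were not called in this comparison, with these numbers of members changed. There were 7 up and 4 down of 14 (adjusted p = 0.0843) among PPAR alpha targets and peroxisome genes, 4 up and 9 down of 24 (adjusted p = 0.647) among hepatocyte identity genes. Counts were 9 up and 7 down of 26 (adjusted p = 0.332) for nuclear receptors and coregulators, 7 up and 4 down of 16 (adjusted p = 0.366) for lipogenesis genes, 6 up and 7 down of 20 (adjusted p = 0.698) for glycolysis genes. For heme synthesis genes they were 2 up and 4 down of 10 (adjusted p = 0.513), for interferon response genes 2 up and 3 down of 21 (adjusted p = 0.739) and for NF-kappaB and acute phase genes 4 up and 4 down of 15 (adjusted p = 0.735). The numbers were 3 up and 7 down of 17 (adjusted p = 0.201) for p53 targets, 5 up and 8 down of 21 (adjusted p = 0.436) for ER stress and ATF4 genes, 0 up and 0 down of 51 (adjusted p = 0.511) for cytosolic ribosome genes. Last, muscle and brown fat genes had 4 up and 0 down of 10 (adjusted p = 0.171) and markers of other cell types had 0 up and 2 down of 14 (adjusted p = 0.591). In all 2396 genes were higher and 2689 lower in wt (adjusted p under 0.05), 660 and 366 of them by at least 2-fold. The limma p-values pool the spread over all 12 arrays, and only 3 of the 11 list calls (oxidative phosphorylation, fatty acid oxidation and cell cycle) held with an estimated correlation.

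The comparison of 2x9 with BGAL asks what this variant changes by itself. From what is known of the constructs, 2x9 carries receptor-binding motifs selective for ERR alpha. APOA4 rose from 119 ± 78.6 to 35750.4 ± 2530.0 (log2 8.24 ± 0.48, adjusted p = 4.05e-09), PCK1 from 36.5 ± 22.9 to 2577 ± 189 and G6PC1 from 368 ± 96.3 to 15066 ± 649.6. GAL3ST1 (6.20 ± 0.31), CREB3L3 (5.64 ± 0.40), ITGB2 (5.39 ± 0.26), RRAGD (5.34 ± 0.24) and CYP17A1 (5.14 ± 0.25) complete the 8 largest increases on the log2 scale. CEMIP, a hyaluronan-binding protein, fell from 8168 ± 600.2 to 477 ± 63.4 (log2 -4.06 ± 0.12). The transcription factor SOX4 fell from 5156 ± 219 to 567 ± 4.97. KRTAP3-1, a keratin-associated protein, changed by log2 -3.80 ± 0.11, the ammonium transporter RHBG by -3.38 ± 0.20, the potassium channel KCNJ10 by -3.37 ± 0.39 and TNS4 by -3.13 ± 0.32. ESRRA rose from 1103 ± 178 to 4798 ± 257; log2 changes were 2.36 ± 0.0992 for NR0B2, 2.35 ± 0.11 for CPT1A, 1.42 ± 0.0892 for ALAS1, 1.01 ± 0.0862 for ACADM and 0.93 ± 0.0575 for CYCS. IDH3A rose by 2.80 ± 0.0761, and its dim probe set gave 0.93 (adjusted p = 0.0941) when those ending in _s_at and _x_at were left out.

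In oxidative phosphorylation 59 of 68 measured members rose and 3 fell (59 and 4 adjusted over the list alone), with a median log2 change of 0.64, NDUFA1 (1.64 ± 0.16) first. For oxidative phosphorylation camera gave adjusted p = 1.63e-18, and adjusted p = 0.052 with an estimated correlation. In the tricarboxylic acid cycle 14 of 19 measured members rose and 2 fell (14 and 3 adjusted over the list alone), with a median log2 change of 0.83, IDH3A and OGDH (1.56 ± 0.12) first. For the tricarboxylic acid cycle camera gave adjusted p = 4.74e-06, and adjusted p = 0.148 with an estimated correlation. In fatty acid oxidation 13 of 21 measured members rose and 4 fell (13 and 5 adjusted over the list alone), with a median log2 change of 0.64, SLC25A20 (2.86 ± 0.0731) first. For fatty acid oxidation camera gave adjusted p = 0.000586, and adjusted p = 0.138 with an estimated correlation. Apolipoprotein and bile acid genes gave this result: 15 of 23 measured members rose and 4 fell (15 and 5 adjusted over the list alone), with a median log2 change of 0.69. After APOA4, BAAT, which conjugates bile acids, rose from 289.7 ± 57.8 to 5867 ± 82.7. For apolipoproteins and bile acids camera gave adjusted p = 0.00128, and adjusted p = 0.116 with an estimated correlation. Mitochondrial ribosome genes went both ways: 33 of 76 measured members rose and 13 fell (35 and 13 adjusted over the list alone), with a median log2 change of 0.17, MRPS11 (2.07 ± 0.11) first. For mitochondrial ribosome genes camera gave adjusted p = 0.00511, and adjusted p = 0.446 with an estimated correlation. For mitochondrial transcription and import 18 of 29 measured members rose and 4 fell (19 and 5 adjusted over the list alone), with a median log2 change of 0.31. For mitochondrial transcription and import camera gave adjusted p = 0.0221, and adjusted p = 0.211 with an estimated correlation. The largest change in that list was a fall, that of the mitochondrial transcription factor TFB1M (-1.45 ± 0.0903).

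Hepatocyte identity genes were lower with 2x9: 5 of 24 measured members rose and 14 fell (5 and 14 adjusted over the list alone), with a median log2 change of -0.35. For hepatocyte identity camera gave adjusted p = 0.00947, and adjusted p = 0.333 with an estimated correlation. CEBPA, a hepatocyte transcription factor, fell from 2247 ± 206 to 637 ± 101. Of cytosolic ribosome genes 34 of 51 measured members rose and 0 fell (37 and 0 adjusted over the list alone), with a median log2 change of 0.22. For cytosolic ribosome genes camera gave adjusted p = 3.29e-05, and adjusted p = 0.513 with an estimated correlation. After quantile normalization that list's mean change relative to other genes was -0.00341 (adjusted p = 0.839). RPL27A, first in it, changed by 0.45 ± 0.15 (adjusted p = 0.0233); its call was lost in 4 of 23 alternatives (adjusted p 0.00154 to 0.103 over them), namely without 2x9 replicate 1 (log2 0.44, adjusted p = 0.06), 2x9 replicate 3 (log2 0.43, adjusted p = 0.0644), BGAL replicate 1 (log2 0.37, adjusted p = 0.0912), BGAL replicate 2 (log2 0.35, adjusted p = 0.103). Without probe sets ending in _s_at and _x_at the calls of mitochondrial transcription and import (adjusted p = 0.183), the mitochondrial ribosome (0.186), hepatocyte identity (0.099) and the cytosolic ribosome (0.387) were lost, the first also as the mean of all probe sets (0.0639). The other 16 lists were not called (camera adjusted p from 0.0639 to 0.858); cell cycle had 8 up and 18 down of 44 (adjusted p = 0.135) and markers of other cell types 2 up and 3 down of 14 (adjusted p = 0.445). For glycolysis and the interferon response the median was positive (0.0624 and 0.0316) while mean and test pointed down. In all 3021 genes were higher and 2956 lower in 2x9, 731 and 734 of them by at least 2-fold, and 0 of the 8 list calls held with an estimated correlation.

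The comparison of L2L3 with BGAL asks what remains when, from what is known of this construct, the motifs through which PGC-1 alpha contacts nuclear receptors are mutated. Changes were fewer and smaller: 1071 genes were higher and 964 lower, 51 and 43 of them by at least 2-fold. Since the expression of the constructs is not known, the smaller response cannot be ascribed to the motifs from these arrays alone. CD177, a neutrophil surface antigen, went from 37.2 ± 19.7 to 238 ± 50.3 (log2 2.34 ± 0.45, adjusted p = 0.00281), and MAS1, an angiotensin peptide receptor, from 53 ± 4.99 to 259.9 ± 50.5. TMC8 (1.86 ± 0.40), FAM3D (1.82 ± 0.54), the keratin KRT20 (1.79 ± 0.29), TMEM88 (1.79 ± 0.46), ARHGAP22-IT1 (1.71 ± 0.47) and TRIM46 (1.62 ± 0.30) complete the 8 largest increases. FGF22, a growth factor, fell from 971 ± 138 to 156 ± 68 (log2 -2.61 ± 0.33). The gene annotated Igk went from 372 ± 45.7 to 88 ± 45.2. PFKFB1 changed by -1.70 ± 0.32, the serine protease TMPRSS2 by -1.63 ± 0.25, chymotrypsin C (CTRC) by -1.59 ± 0.30 and the glucokinase regulator GCKR by -1.58 ± 0.28. The FAM3D call was lost in 8 of 23 alternatives (adjusted p 0.00772 to 0.13 over them), among them without BGAL replicate 1 (log2 1.79, adjusted p = 0.0791), BGAL replicate 2 (log2 1.80, adjusted p = 0.0791), BGAL replicate 3 (log2 1.85, adjusted p = 0.0718), L2L3 replicate 2 (log2 1.56, adjusted p = 0.13), L2L3 replicate 3 (log2 1.80, adjusted p = 0.0865). TMEM88 lost its call without BGAL replicate 1 (log2 1.67, adjusted p = 0.0509), BGAL replicate 2 (log2 1.52, adjusted p = 0.0624), L2L3 replicate 2 (log2 1.41, adjusted p = 0.0846), and ARHGAP22-IT1 without BGAL replicate 1 (log2 1.33, adjusted p = 0.0912), BGAL replicate 3 (log2 1.49, adjusted p = 0.0818), L2L3 replicate 1 (log2 1.53, adjusted p = 0.0816).

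Of the genes fixed in advance, NR0B2 fell with L2L3 from 1864 ± 74.8 to 1087 ± 125 (log2 -0.78 ± 0.0992, adjusted p = 0.000202). ESRRA was at log2 0.36 ± 0.11 (adjusted p = 0.0422) through its brightest probe set, while its other probe set was called lower (-0.47), and the mean of both gave -0.0577. That call was lost in 14 of 24 alternatives (adjusted p 0.00856 to 0.748 over them), among them without 2x9 replicate 1 (log2 0.36, adjusted p = 0.0514), 2x9 replicate 2 (log2 0.36, adjusted p = 0.052), 2x9 replicate 3 (log2 0.36, adjusted p = 0.054), BGAL replicate 2 (log2 0.39, adjusted p = 0.0645), BGAL replicate 3 (log2 0.22, adjusted p = 0.164), L2L3 replicate 1 (log2 0.27, adjusted p = 0.157), L2L3 replicate 2 (log2 0.39, adjusted p = 0.0647), L2L3 replicate 3 (log2 0.40, adjusted p = 0.0547), wt replicate 2 (log2 0.36, adjusted p = 0.0535). IDH3A (0.30 ± 0.0761) lost its call in 6 of 24 alternatives (adjusted p 0.00665 to 0.496 over them), among them without BGAL replicate 3 (log2 0.23, adjusted p = 0.0616), L2L3 replicate 1 (log2 0.27, adjusted p = 0.0598), L2L3 replicate 2 (log2 0.29, adjusted p = 0.0513). CYCS (0.22 ± 0.0575) lost its own in 6 of 24 alternatives (adjusted p 0.0135 to 0.256 over them), among them without BGAL replicate 1 (log2 0.18, adjusted p = 0.0579), L2L3 replicate 2 (log2 0.19, adjusted p = 0.0816). Not called were PCK1 (0.52 ± 0.25, adjusted p = 0.198), G6PC1 (0.13 ± 0.16, adjusted p = 0.645), CPT1A (-0.31 ± 0.11, adjusted p = 0.0718), ACADM (-0.24 ± 0.0862, adjusted p = 0.0742) and ALAS1 (-0.0353 ± 0.0892, adjusted p = 0.849). PCK1 was called without BGAL replicate 1 (log2 0.86, adjusted p = 0.00999), ACADM without L2L3 replicate 1 (log2 -0.31, adjusted p = 0.0421), wt replicate 1 (log2 -0.24, adjusted p = 0.0382), and CPT1A without 2x9 replicate 2 (log2 -0.31, adjusted p = 0.0231). The sign changed for G6PC1 without BGAL replicate 1 (log2 -0.0892, adjusted p = 0.71) and for ALAS1 without BGAL replicate 3 (log2 0.0516, adjusted p = 0.775), L2L3 replicate 3 (log2 0.0361, adjusted p = 0.859).

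With L2L3, oxidative phosphorylation genes were higher: 25 of 68 measured members rose and 0 fell (31 and 1 adjusted over the list alone), with a median log2 change of 0.19. For oxidative phosphorylation camera gave adjusted p = 4.62e-09, and adjusted p = 0.116 with an estimated correlation. UQCRB, first in that list, changed by 0.93 ± 0.11, and by 0.0563 (adjusted p = 0.894) without probe sets ending in _s_at and _x_at. Of cytosolic ribosome genes 18 of 51 measured members rose and 0 fell (35 and 0 adjusted over the list alone), with a median log2 change of 0.20, RPS23 (0.31 ± 0.0569) first. For cytosolic ribosome genes camera gave adjusted p = 2.39e-12, and adjusted p = 0.322 with an estimated correlation. Quantile normalization kept the call of that list and ended that of RPS23 (adjusted p = 0.0557). In the mitochondrial ribosome 19 of 76 measured members rose and 1 fell (23 and 1 adjusted over the list alone), with a median log2 change of 0.13, MRPS15 (0.66 ± 0.0919) first, whose call was lost without probe sets ending in _s_at and _x_at (adjusted p = 0.652). For mitochondrial ribosome genes camera gave adjusted p = 7.53e-06, and adjusted p = 0.266 with an estimated correlation. Of mitochondrial transcription and import genes 5 of 29 measured members rose and 0 fell (6 and 0 adjusted over the list alone), with a median log2 change of 0.097, TOMM22 (0.84 ± 0.11) first. For mitochondrial transcription and import camera gave adjusted p = 0.026, and adjusted p = 0.225 with an estimated correlation.

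Cell cycle genes were lower with L2L3: 1 of 44 measured members rose and 15 fell (2 and 23 adjusted over the list alone), with a median log2 change of -0.25. For cell cycle genes camera gave adjusted p = 3.09e-07, and adjusted p = 0.052 with an estimated correlation. PLK1, first among them, changed by -0.48 ± 0.15 (adjusted p = 0.0461), a call lost in 12 of 24 alternatives (adjusted p 0.0039 to 0.126 over them), among them without BGAL replicate 1 (log2 -0.48, adjusted p = 0.0962), BGAL replicate 2 (log2 -0.45, adjusted p = 0.119), BGAL replicate 3 (log2 -0.50, adjusted p = 0.0795), L2L3 replicate 1 (log2 -0.50, adjusted p = 0.0793), L2L3 replicate 2 (log2 -0.44, adjusted p = 0.126), L2L3 replicate 3 (log2 -0.48, adjusted p = 0.0982), wt replicate 2 (log2 -0.48, adjusted p = 0.0516). Of PPAR alpha targets and peroxisome genes 0 of 14 measured members rose and 5 fell (0 and 5 adjusted over the list alone), with a median log2 change of -0.14, the pantetheinase VNN1 (-1.50 ± 0.33) first. For PPAR alpha and peroxisome genes camera gave adjusted p = 0.00823, and adjusted p = 0.0794 with an estimated correlation. In fatty acid oxidation 1 of 21 measured members rose and 3 fell (1 and 3 adjusted over the list alone), with a median log2 change of -0.16, ACSL1, which activates fatty acids, first (-0.89 ± 0.0854). For fatty acid oxidation camera gave adjusted p = 0.0254, and adjusted p = 0.302 with an estimated correlation. Among nuclear receptors and coregulators 1 of 26 measured members rose and 3 fell (1 and 3 adjusted over the list alone), with a median log2 change of -0.16, the corepressor NRIP1 (-0.52 ± 0.0639) first. For nuclear receptors and coregulators camera gave adjusted p = 0.0422, and adjusted p = 0.123 with an estimated correlation. Of ER stress and ATF4 genes 3 of 21 measured members rose and 8 fell (3 and 8 adjusted over the list alone), with a median log2 change of -0.14. For ER stress and ATF4 camera gave adjusted p = 0.0487, and adjusted p = 0.134 with an estimated correlation. HSP90B1, an ER chaperone, had the largest change there, a rise of 1.16 ± 0.12, but its other probe set was called lower (-0.82) and the mean of both was not called (adjusted p = 0.108).

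Several of these list calls in L2L3 were lost without single arrays and under other settings. Fatty acid oxidation lost its call without BGAL replicate 1 (adjusted p = 0.0585), L2L3 replicate 3 (adjusted p = 0.0518), and without probe sets ending in _s_at and _x_at (0.124). Mitochondrial transcription and import lost its call without BGAL replicate 3 (adjusted p = 0.116), and with the filter at the 70th percentile (0.0619), after quantile normalization (0.0548) and without probe sets ending in _s_at and _x_at (0.213). Nuclear receptors and coregulators lost theirs without BGAL replicate 1 (adjusted p = 0.0549), BGAL replicate 2 (adjusted p = 0.0623), L2L3 replicate 2 (adjusted p = 0.139), and with the filter at the 70th percentile (0.0731), after quantile normalization (0.0627), without probe sets ending in _s_at and _x_at (0.271) and with the replicate block (0.0547). For ER stress and ATF4 genes the call was lost without 2x9 replicate 1 (adjusted p = 0.0605), 2x9 replicate 2 (adjusted p = 0.0511), BGAL replicate 1 (adjusted p = 0.0652), BGAL replicate 2 (adjusted p = 0.0692), BGAL replicate 3 (adjusted p = 0.0628), L2L3 replicate 1 (adjusted p = 0.0745), L2L3 replicate 2 (adjusted p = 0.0688), wt replicate 3 (adjusted p = 0.0506), and with the filter at the 70th percentile (0.0714), without probe sets ending in _s_at and _x_at (0.21), with the replicate block (0.0501) and with eBayes without the trend (0.056). The other 15 lists were not called (camera adjusted p from 0.0632 to 0.867). In antioxidant and uncoupling genes, glycolysis, p53 targets and markers of other cell types, median, mean and test differed in sign. None of the 9 list calls held with an estimated correlation (0 of 9).

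The direct comparison of wt with 2x9 asks which responses the variant does not share in size. FOS, an immediate early transcription factor, read 475 ± 40.2 in 2x9 and 27.1 ± 4.68 in wt (log2 -3.58 ± 0.47, adjusted p = 5.05e-05), and CCNE2 2071 ± 152 in 2x9 and 417 ± 29.6 in wt (log2 -2.28 ± 0.0955). Also lower in wt were the laminin subunit LAMB3 (-2.64 ± 0.53), ARHGAP33 (-2.51 ± 0.68), BTG3 (-2.15 ± 0.0821) and CLRN3 (-2.11 ± 0.52). ARHGAP33 lost its call without wt replicate 1 (log2 -1.75, adjusted p = 0.055). BTG3 was lower in wt through its brightest probe set, but without probe sets ending in _s_at and _x_at it was higher (0.51, adjusted p = 0.0017). PSMB8, an immunoproteasome subunit, was at 391 ± 74.3 in wt and 28.7 ± 13.3 in 2x9 (log2 3.27 ± 0.30). RHBG (2.82 ± 0.20), the nucleoside transporter SLC29A4 (2.79 ± 0.26), TRIM50 (2.55 ± 0.45), HEG1 (2.55 ± 0.29), HGFAC (2.38 ± 0.40) and TMEM72 (2.31 ± 0.35) were also higher in wt. SLC51A, part of a bile acid transporter, completes these 8 and was at 462 ± 13.8 in wt and 70.7 ± 10.3 in 2x9.

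Genes fixed in advance differed in both directions between wt and 2x9. CPT1A (0.65 ± 0.11) and ACADM (0.32 ± 0.0862) were higher in wt. G6PC1 (-1.42 ± 0.16), PCK1 (-0.85 ± 0.25), NR0B2 (-0.60 ± 0.0992), ALAS1 (-0.35 ± 0.0892), IDH3A (-0.38 ± 0.0761) and CYCS (-0.16 ± 0.0575) were lower in wt. ESRRA was not called (-0.17 ± 0.11, adjusted p = 0.273, 95% interval -0.41 to 0.0686). The ACADM call was lost without wt replicate 3 (log2 0.25, adjusted p = 0.0552), and that of PCK1 without 2x9 replicate 2 (log2 -0.83, adjusted p = 0.061), 2x9 replicate 3 (log2 -0.80, adjusted p = 0.068), wt replicate 1 (log2 -0.72, adjusted p = 0.0887) and without a pseudocount (adjusted p = 0.0594). CYCS lost its call in 14 of 24 alternatives (adjusted p 0.0253 to 0.488 over them), among them without 2x9 replicate 1 (log2 -0.16, adjusted p = 0.11), 2x9 replicate 2 (log2 -0.17, adjusted p = 0.0722), 2x9 replicate 3 (log2 -0.16, adjusted p = 0.0946), BGAL replicate 2 (log2 -0.16, adjusted p = 0.0537), L2L3 replicate 1 (log2 -0.16, adjusted p = 0.0549), L2L3 replicate 3 (log2 -0.16, adjusted p = 0.0507), wt replicate 2 (log2 -0.12, adjusted p = 0.172), wt replicate 3 (log2 -0.17, adjusted p = 0.0673), and turned to 0.0426 after quantile normalization and 0.21 as the mean of its probe sets. For IDH3A another probe set was called higher in wt (0.72), and the call was lost as the mean of all probe sets (adjusted p = 0.9) and without those ending in _s_at and _x_at (0.499).

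Lipogenesis genes separated the 2 constructs: 12 of 16 measured members were higher in wt and 0 lower (12 and 0 adjusted over the list alone), with a median log2 change of 0.59. For lipogenesis camera gave adjusted p = 1.45e-06, and adjusted p = 0.022 with an estimated correlation. GPAM, which starts glycerolipid synthesis, was at 1222 ± 129 in wt and 423 ± 81.3 in 2x9, against 2409 ± 542 in BGAL. In fatty acid oxidation 14 of 21 measured members were higher in wt and 0 lower (14 and 0 adjusted over the list alone), with a median log2 change of 0.42, CPT2 (1.07 ± 0.18) first. For fatty acid oxidation camera gave adjusted p = 7.97e-05, and adjusted p = 0.114 with an estimated correlation. In oxidative phosphorylation 32 of 68 measured members were higher in wt and 1 lower (39 and 1 adjusted over the list alone), with a median log2 change of 0.20. For oxidative phosphorylation camera gave adjusted p = 2.2e-06, and adjusted p = 0.182 with an estimated correlation. NDUFV3 led that list (0.67 ± 0.13) and lost its call without probe sets ending in _s_at and _x_at (adjusted p = 0.289). In the tricarboxylic acid cycle 10 of 19 measured members were higher in wt and 1 lower (12 and 1 adjusted over the list alone), with a median log2 change of 0.25, IDH2 (1.45 ± 0.0922) first. For the tricarboxylic acid cycle camera gave adjusted p = 0.00221, and adjusted p = 0.302 with an estimated correlation. Of hepatocyte identity genes 11 of 24 measured members were higher in wt and 0 lower (11 and 0 adjusted over the list alone), with a median log2 change of 0.25, CEBPA (1.28 ± 0.14) first. For hepatocyte identity camera gave adjusted p = 0.000379, and adjusted p = 0.206 with an estimated correlation. In the mitochondrial ribosome 23 of 76 measured members were higher in wt and 7 lower (24 and 8 adjusted over the list alone), with a median log2 change of 0.096. For mitochondrial ribosome genes camera gave adjusted p = 0.0154, and adjusted p = 0.494 with an estimated correlation. Quantile normalization (adjusted p = 0.0806) and the filter at the 70th percentile (0.082) ended that call. MRPL33, first in it at -1.12 ± 0.41 (adjusted p = 0.0487), lost its call in 12 of 24 alternatives (adjusted p 0.0153 to 0.186 over them), among them without 2x9 replicate 1 (log2 -1.02, adjusted p = 0.129), 2x9 replicate 3 (log2 -0.88, adjusted p = 0.171), BGAL replicate 2 (log2 -1.12, adjusted p = 0.0507), L2L3 replicate 2 (log2 -1.12, adjusted p = 0.0586), wt replicate 1 (log2 -1.18, adjusted p = 0.0832), wt replicate 2 (log2 -0.84, adjusted p = 0.186).

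Cell cycle genes were lower in wt than in 2x9: 1 of 44 measured members were higher in wt and 29 lower (1 and 29 adjusted over the list alone), with a median log2 change of -0.54. For cell cycle genes camera gave adjusted p = 1.56e-12, and adjusted p = 0.022 with an estimated correlation. Of cytosolic ribosome genes 0 of 51 measured members were higher in wt and 24 lower (0 and 34 adjusted over the list alone), with a median log2 change of -0.19. For cytosolic ribosome genes camera gave adjusted p = 8.75e-07, and adjusted p = 0.46 with an estimated correlation. Quantile normalization ended that call (adjusted p = 0.494), as did leaving out probe sets ending in _s_at and _x_at (0.0661). RPL27A (-0.46 ± 0.15) had the largest change there and lost its call in 5 of 23 alternatives (adjusted p 0.00775 to 0.127 over them), among them without 2x9 replicate 1 (log2 -0.45, adjusted p = 0.0785), 2x9 replicate 3 (log2 -0.43, adjusted p = 0.0844), wt replicate 1 (log2 -0.48, adjusted p = 0.0605), wt replicate 2 (log2 -0.36, adjusted p = 0.127). The other 16 lists were not called (camera adjusted p from 0.276 to 0.948). Median, mean and test differed in sign for PPAR alpha targets, gluconeogenesis, xenobiotic metabolism, p53 targets and markers of other cell types. In all 2091 genes were higher and 1937 lower in wt, 228 and 199 by at least 2-fold, and 2 of the 8 list calls (lipogenesis and cell cycle) held with an estimated correlation.

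**Figure D2:**
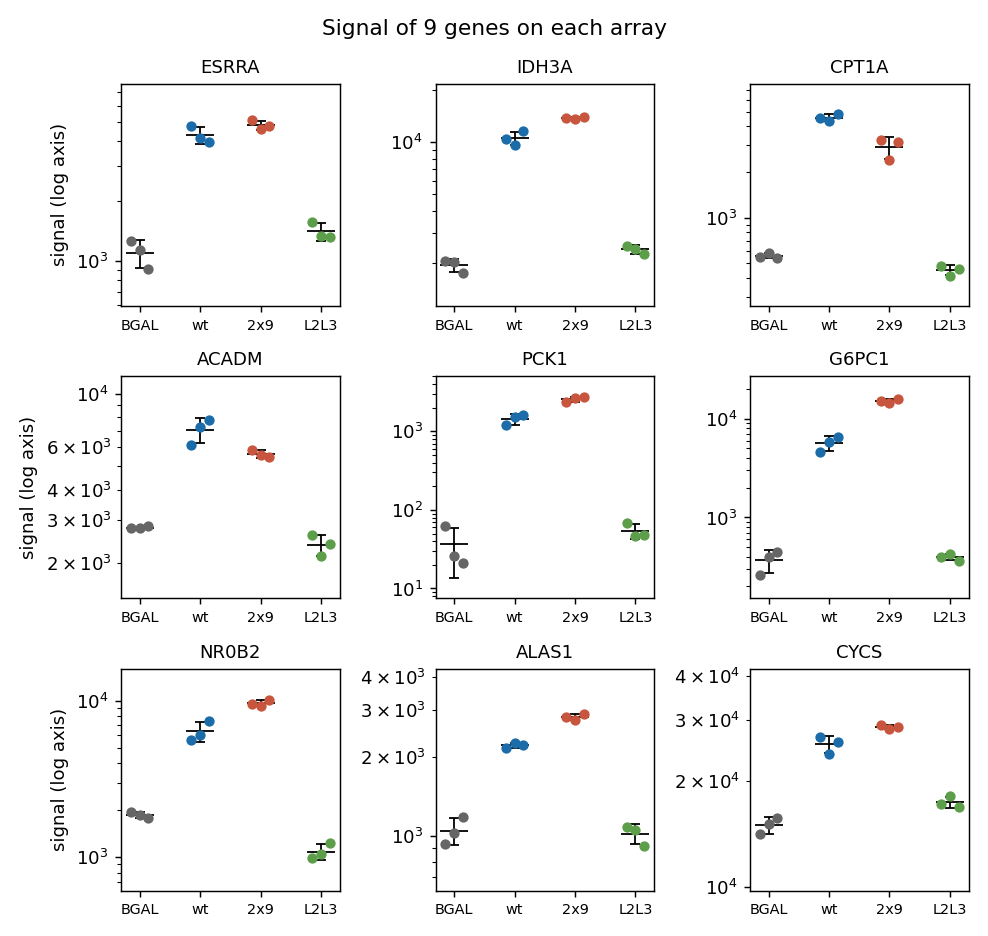
Signal (y axis, log scale) of 9 genes fixed in advance in BGAL, wt, 2x9 and L2L3; coloured points are arrays, and black bars the mean ± SD of 3 arrays. Through its brightest probe set CPT1A averaged 561 in BGAL, 4579 in wt, 2940.0 in 2x9 and 452 in L2L3, and G6PC1 368, 5669, 15066 and 396.

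The comparison of wt with L2L3 sets wild-type PGC-1 against the motif mutant in place of the control virus. APOA4 was at 18738 ± 1749.6 in wt and 87 ± 91.8 in L2L3 (log2 7.93 ± 0.48, adjusted p = 9.79e-09). The other genes of the 8 largest increases were GAL3ST1 (6.24 ± 0.31), OGDHL (5.72 ± 0.26), MMP20, a tooth enamel metalloprotease (5.02 ± 0.33), CYP17A1 (4.97 ± 0.25), ITGB2 (4.88 ± 0.26), CYP7A1 (4.52 ± 0.41) and RRAGD (4.47 ± 0.24). EREG read 23.9 ± 13.9 in wt and 1051 ± 116 in L2L3 (log2 -4.89 ± 0.38), and EGR1, an immediate early transcription factor, 349.6 ± 6.83 and 3344 ± 61.5. IGFBP1 (-3.05 ± 0.0891), IER3 (-2.98 ± 0.0782), the cytokine IL11 (-2.85 ± 0.36) and TNS4 (-2.82 ± 0.32) were also lower in wt. Of the genes fixed in advance, PCK1 (4.40 ± 0.25), G6PC1 (3.78 ± 0.16), CPT1A (3.30 ± 0.11), NR0B2 (2.53 ± 0.0992), ESRRA (1.59 ± 0.11), ACADM (1.57 ± 0.0862), ALAS1 (1.11 ± 0.0892) and CYCS (0.55 ± 0.0575) were higher in wt. IDH3A was higher as well (2.12 ± 0.0761), but its dim probe set gave -0.0170 (adjusted p = 0.982) without those ending in _s_at and _x_at. That dim probe set read 172 ± 37.2 in wt and 180 ± 66.0 in L2L3. The other IDH3A probe set ending in _s_at read 3646 ± 94.3 and 754 ± 33.7.

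All fatty acid oxidation genes measured were higher in wt than in L2L3: 21 of 21 measured members were higher in wt and 0 lower (21 and 0 adjusted over the list alone), with a median log2 change of 0.99. For fatty acid oxidation camera gave adjusted p = 2.05e-16, and adjusted p = 0.022 with an estimated correlation. In oxidative phosphorylation 60 of 68 measured members were higher in wt and 0 lower (63 and 0 adjusted over the list alone), with a median log2 change of 0.63, NDUFA8 (1.66 ± 0.0642) first. For oxidative phosphorylation camera gave adjusted p = 1.3e-29, and adjusted p = 0.022 with an estimated correlation. In the tricarboxylic acid cycle 18 of 19 measured members were higher in wt and 0 lower (18 and 0 adjusted over the list alone), with a median log2 change of 0.88, MPC1 (2.18 ± 0.11) first. For the tricarboxylic acid cycle camera gave adjusted p = 3.88e-14, and adjusted p = 0.052 with an estimated correlation. Of PPAR alpha targets and peroxisome genes 9 of 14 measured members were higher in wt and 2 lower (9 and 2 adjusted over the list alone), with a median log2 change of 0.73, CREB3L3 (4.25 ± 0.40) first. For PPAR alpha and peroxisome genes camera gave adjusted p = 0.00148, and adjusted p = 0.052 with an estimated correlation. In gluconeogenesis 6 of 11 measured members were higher in wt and 1 lower (6 and 1 adjusted over the list alone), with a median log2 change of 0.68. For gluconeogenesis camera gave adjusted p = 0.0045, and adjusted p = 0.0714 with an estimated correlation. Among apolipoprotein and bile acid genes 15 of 23 measured members were higher in wt and 2 lower (15 and 2 adjusted over the list alone), with a median log2 change of 0.64. For apolipoproteins and bile acids camera gave adjusted p = 2.52e-07, and adjusted p = 0.052 with an estimated correlation. In the mitochondrial ribosome 27 of 76 measured members were higher in wt and 12 lower (28 and 13 adjusted over the list alone), with a median log2 change of 0.10, MRPL34 (1.66 ± 0.0692) first. For mitochondrial ribosome genes camera gave adjusted p = 0.0045, and adjusted p = 0.441 with an estimated correlation.

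Of antioxidant and uncoupling genes 7 of 19 measured members were higher in wt and 1 lower (7 and 1 adjusted over the list alone), with a median log2 change of 0.13, SLC25A4 (2.36 ± 0.0717) first. For antioxidant and uncoupling genes camera gave adjusted p = 0.00951, and adjusted p = 0.114 with an estimated correlation. Among nuclear receptors and coregulators 10 of 26 measured members were higher in wt and 4 lower (10 and 4 adjusted over the list alone), with a median log2 change of 0.0848, ESRRA first. For nuclear receptors and coregulators camera gave adjusted p = 0.0265, and adjusted p = 0.114 with an estimated correlation. That call was lost without L2L3 replicate 2 (adjusted p = 0.0585) and with the filter at the 70th percentile (0.077). In cholesterol synthesis 6 of 15 measured members were higher in wt and 0 lower (6 and 0 adjusted over the list alone), with a median log2 change of 0.0718, NSDHL (0.76 ± 0.082) first. For cholesterol synthesis camera gave adjusted p = 0.0194, and adjusted p = 0.139 with an estimated correlation, and the call was lost without probe sets ending in _s_at and _x_at (0.0614). In xenobiotic metabolism 5 of 12 measured members were higher in wt and 0 lower (5 and 1 adjusted over the list alone), with a median log2 change of 0.37, the P450 reductase gene POR (1.97 ± 0.0796) first. For xenobiotic metabolism camera gave adjusted p = 0.00635, and adjusted p = 0.0794 with an estimated correlation. Cell cycle genes were lower: 2 of 44 measured members were higher in wt and 33 lower (2 and 34 adjusted over the list alone), with a median log2 change of -0.52, CCNE2 (-1.78 ± 0.0955) first. For cell cycle genes camera gave adjusted p = 7.45e-08, and adjusted p = 0.052 with an estimated correlation. Of cytosolic ribosome genes 0 of 51 measured members were higher in wt and 24 lower (0 and 27 adjusted over the list alone), with a median log2 change of -0.17. For cytosolic ribosome genes camera gave adjusted p = 0.000104, and adjusted p = 0.544 with an estimated correlation. Quantile normalization ended that call (adjusted p = 0.0701). RPL27A (-0.41 ± 0.15) had the largest change there and lost its call in 11 of 23 alternatives (adjusted p 0.0145 to 0.165 over them), among them without 2x9 replicate 1 (log2 -0.41, adjusted p = 0.0544), 2x9 replicate 2 (log2 -0.41, adjusted p = 0.0521), 2x9 replicate 3 (log2 -0.41, adjusted p = 0.0529), L2L3 replicate 2 (log2 -0.33, adjusted p = 0.154), L2L3 replicate 3 (log2 -0.36, adjusted p = 0.128), wt replicate 1 (log2 -0.43, adjusted p = 0.0746), wt replicate 2 (log2 -0.31, adjusted p = 0.165). The other 11 lists were not called (camera adjusted p from 0.0632 to 0.967); for hepatocyte identity and p53 targets median and mean differed in sign. In all 2196 genes were higher and 2831 lower in wt than in L2L3, 665 and 243 by at least 2-fold, and 2 of the 13 list calls (oxidative phosphorylation and fatty acid oxidation) held with an estimated correlation.

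The comparison of 2x9 with L2L3 sets the ERR alpha-selective variant against the motif mutant. APOA4 was at 35750.4 ± 2530.0 in 2x9 and 87 ± 91.8 in L2L3 (log2 8.86 ± 0.48, adjusted p = 2.76e-09), followed by GAL3ST1 (6.52 ± 0.31), CYP17A1 (5.67 ± 0.25), MMP20 (5.44 ± 0.33), PCK1 (5.25 ± 0.25), G6PC1 (5.20 ± 0.16), RRAGD (5.16 ± 0.24) and CREB3L3 (4.96 ± 0.40). KRTAP3-1 was at 182 ± 27.8 in 2x9 and 4299 ± 260.5 in L2L3 (log2 -4.46 ± 0.11). CEMIP (-3.52 ± 0.12), EREG (-3.52 ± 0.38), B4GALNT4 (-3.04 ± 0.30), PSMB8 (-2.97 ± 0.30) and RHBG (-2.95 ± 0.20) were also lower in 2x9, though a dimmer probe set of B4GALNT4 was called higher (0.73). NR0B2 (3.14 ± 0.0992), CPT1A (2.65 ± 0.11), ESRRA (1.76 ± 0.11), ALAS1 (1.46 ± 0.0892), ACADM (1.25 ± 0.0862) and CYCS (0.71 ± 0.0575) were higher in 2x9. IDH3A was higher too, at 13704 ± 244 in 2x9 and 2406 ± 132 in L2L3, and not called through its dim probe set alone (0.41, adjusted p = 0.501).

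In oxidative phosphorylation 54 of 68 measured members were higher in 2x9 and 3 lower (55 and 3 adjusted over the list alone), with a median log2 change of 0.50, NDUFA1 (1.28 ± 0.16) first. For oxidative phosphorylation camera gave adjusted p = 5.38e-17, and adjusted p = 0.052 with an estimated correlation. In the tricarboxylic acid cycle 14 of 19 measured members were higher in 2x9 and 2 lower (14 and 2 adjusted over the list alone), with a median log2 change of 0.62. For the tricarboxylic acid cycle camera gave adjusted p = 3.09e-07, and adjusted p = 0.116 with an estimated correlation. In fatty acid oxidation 13 of 21 measured members were higher in 2x9 and 3 lower (15 and 3 adjusted over the list alone), with a median log2 change of 0.72, SLC25A20 (2.75 ± 0.0731) first. For fatty acid oxidation camera gave adjusted p = 2.11e-07, and adjusted p = 0.0521 with an estimated correlation. Among apolipoprotein and bile acid genes 15 of 23 measured members were higher in 2x9 and 3 lower (15 and 4 adjusted over the list alone), with a median log2 change of 0.67. For apolipoproteins and bile acids camera gave adjusted p = 8.07e-05, and adjusted p = 0.0794 with an estimated correlation. Of PPAR alpha targets and peroxisome genes 8 of 14 measured members were higher in 2x9 and 3 lower (8 and 3 adjusted over the list alone), with a median log2 change of 0.61. For PPAR alpha and peroxisome genes camera gave adjusted p = 0.0154, and adjusted p = 0.107 with an estimated correlation. In gluconeogenesis 5 of 11 measured members were higher in 2x9 and 1 lower (5 and 1 adjusted over the list alone), with a median log2 change of 0.28. For gluconeogenesis camera gave adjusted p = 0.0287, and adjusted p = 0.121 with an estimated correlation. In xenobiotic metabolism 5 of 12 measured members were higher in 2x9 and 0 lower (5 and 0 adjusted over the list alone), with a median log2 change of 0.37, CYP1A1 (2.04 ± 0.15) first. For xenobiotic metabolism camera gave adjusted p = 0.0154, and adjusted p = 0.107 with an estimated correlation. Hepatocyte identity genes were lower in 2x9: 3 of 24 measured members were higher in 2x9 and 10 lower (3 and 12 adjusted over the list alone), with a median log2 change of -0.25, although its largest change was a rise, that of the coagulation factor F10 (2.06 ± 0.15). For hepatocyte identity camera gave adjusted p = 0.02, and adjusted p = 0.389 with an estimated correlation, and the call was lost with the filter at the 70th percentile (0.0728) and without probe sets ending in _s_at and _x_at (0.248). The other 16 lists were not called (camera adjusted p from 0.0638 to 0.808); for the mitochondrial ribosome, glycolysis, the interferon response and ER stress, median, mean and test differed in sign. In all 2341 genes were higher and 2820 lower in 2x9, 655 and 430 by at least 2-fold, and 0 of the 8 list calls held with an estimated correlation.

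**Figure D3:**
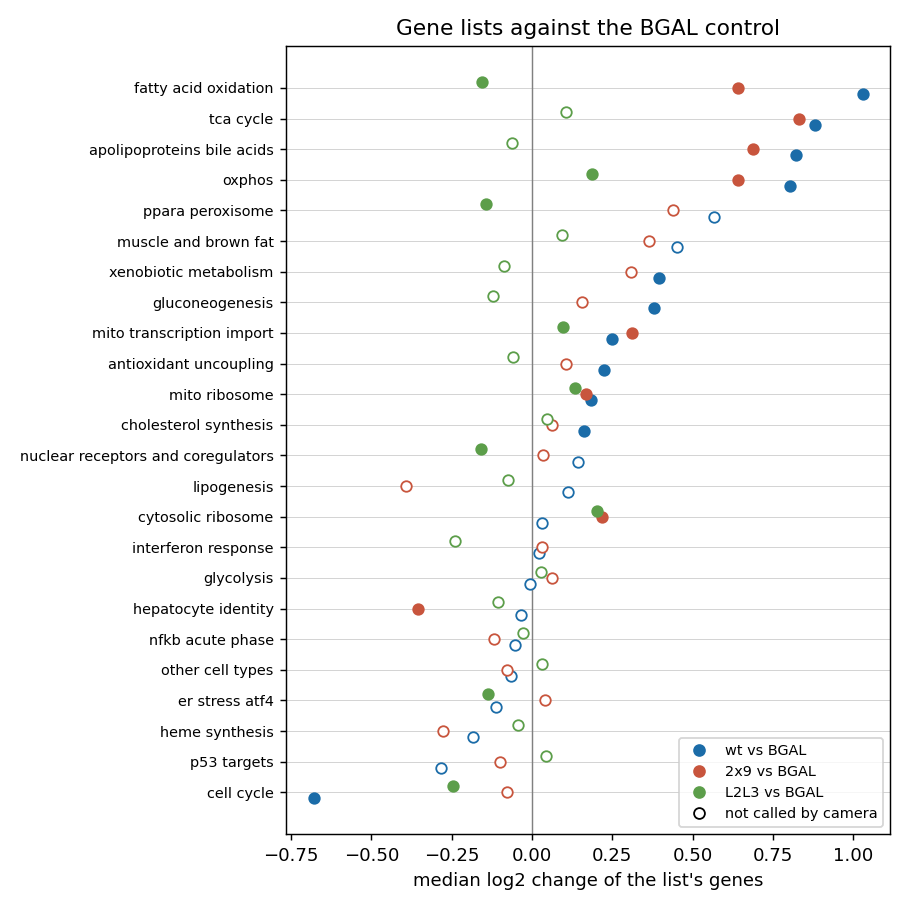
Median log2 change against BGAL (x axis) of the genes of 24 lists (y axis) for wt, 2x9 and L2L3; filled points were called by camera (adjusted p under 0.05, preset correlation) and open points were not. The median of oxidative phosphorylation (oxphos) was 0.80 with wt, 0.64 with 2x9 and 0.19 with L2L3, and the cytosolic ribosome call for 2x9 was lost after quantile normalization (mean relative change -0.00341).

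Shared responses were counted to ask how much of the response to wt PGC-1 was also seen with each variant. Of the 2396 genes raised by wt, 1807 (75.4%) were also raised by 2x9, where independent lists of these sizes would share 572. Of the 2689 genes lowered by wt, 1834 were lowered by 2x9 (628 for independent lists). L2L3 raised 522 (21.8%) of the genes raised by wt (203 for independent lists). These pairs share the BGAL arrays. Simulated arrays without any change gave at most 1 shared call in 50 simulations. The simulated correlation of log2 changes across genes was 0.497 for wt and 2x9 and 0.499 for wt and L2L3. The measured correlations were 0.774 and 0.311. Arrays without change hold only noise, so neither the simulated calls nor the simulated correlations are a baseline for them. On the scale of covariance the measured values were 0.346 and 0.0647, above the simulated 0.0255 and 0.0256. Genes are not independent replicates. Without a shared array, 1503 (62.7%) of the genes raised by wt were also higher in 2x9 than in L2L3 (443 for independent lists), and the correlation across genes was 0.689. Of the 660 genes that wt raised at least 2-fold, 609 were raised by 2x9, 607 were higher in wt than in L2L3, and 105 were raised by L2L3. Of the same 660, 194 were higher and 69 lower in wt than in 2x9 (109 and 101 for independent lists). The 660 were selected through the wt arrays, which also enter the comparisons of wt with 2x9 and L2L3. Noise in those arrays favours genes higher in wt. Among the 1807 genes raised by both wt and 2x9, 286 were higher in wt and 320 higher in 2x9 (299 and 277 for independent lists). A total of 1155 genes were raised by wt and by 2x9 and higher in 2x9 than in L2L3, without being called higher in L2L3 than in BGAL.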

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

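The results in this part were found by rules fixed before the data were examined; SORL1, ADGRG1, SGCB and PMAIP1 were chosen as examples after their values were seen. The effects of wt and 2x9 against BGAL differed in direction for some genes, with the difference itself tested. There were 75 genes raised by wt, lowered by 2x9 and higher in wt than in 2x9, among them CD36, a fatty acid uptake receptor (log2 0.98 with wt and -1.04 with 2x9), TMEM72 (1.05 and -1.26), ADGRG1 (0.69 and -0.82) and SORL1 (0.63 and -1.55). Another 100 genes were lowered by wt, raised by 2x9 and lower in wt than in 2x9, among them BTG3, SGCB and PMAIP1; for 15 of the 175 genes, BTG3 among them, another probe set was called the opposite way in 2x9. Independent lists of these sizes would share 559.5 and 642 genes.

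Signal outside the gene comparisons was also tested. Of the 4593 probe sets above the filter without a single listed gene, 918 changed in wt against BGAL, 1184 in 2x9 against BGAL and 225 in L2L3 against BGAL.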

How the results depend on the processing

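The settings in this part were chosen before the data were examined. Counts of changed genes for wt vs BGAL, 2x9 vs BGAL, L2L3 vs BGAL, wt vs 2x9, wt vs L2L3 and 2x9 vs L2L3 stayed within 1.5 times the main count under the settings tried, with these exceptions. With a minimum of 2-fold they were 1026, 1465, 94, 427, 908 and 1085, because a size was added to the threshold. That minimum left 464 genes raised by wt and by 2x9, 414 raised by wt and higher in 2x9 than L2L3, 25 raised by wt and L2L3, and 36 raised by wt and higher in wt than 2x9. Without probe sets ending in _s_at and _x_at, L2L3 vs BGAL had 1280 genes and 311 were raised by wt and L2L3, with fewer genes tested. With an estimated correlation 7 of the 57 list calls held. A correlation above the preset 0.01 weakens a call, and the estimate was 0.113 for oxidative phosphorylation and 0.578 for the cytosolic ribosome. For gluconeogenesis it was -0.0451, and the calls of that list were lost as well. The size of the correlation is thus not the whole cause, and the rest was not tested. With the replicate block the counts were 5060, 5982, 2049, 4037, 5030 and 5165, the overlaps 1807, 1519, 522 and 688, and 55 list calls held.

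Leaving out 1 array at a time gave 4515 to 5062 genes for wt vs BGAL, 5412 to 5944 for 2x9 vs BGAL, 1399 to 2005 for L2L3 vs BGAL, 3364 to 4081 for wt vs 2x9, 4411 to 5075 for wt vs L2L3 and 4632 to 5194 for 2x9 vs L2L3. Overlaps ranged over 1660 to 1804 (wt and 2x9), 1379 to 1479 (wt, 2x9 over L2L3), 395 to 505 (wt and L2L3) and 534 to 686 (wt over 2x9), and 54 to 57 list calls held.

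Over the 505 gene results the alternatives kept direction and call 11471 times, ended a call with its direction kept 414 times, added one 4 times and reversed a direction 11 times. Over the 57 list calls they kept 1385, ended 96 and reversed 1. The reversals were as follows, and their cause was not tested. Without probe sets ending in _s_at and _x_at, SC5D was at -0.44 in 2x9 vs BGAL and -0.21 in L2L3 vs BGAL, LYZ at -0.15 in L2L3 vs BGAL, BTG3 at 0.51 in wt vs 2x9 and IDH3A at -0.0170 in wt vs L2L3. As the mean of all probe sets, ESRRA was at -0.0577 in L2L3 vs BGAL and CYCS at 0.21 in wt vs 2x9. Quantile normalization put CYCS at 0.0426 in wt vs 2x9 and the cytosolic ribosome list at -0.00341 in 2x9 vs BGAL. Without BGAL replicate 1, G6PC1 was at -0.0892 in L2L3 vs BGAL (range without 1 array -0.0892 to 0.28). ALAS1 there was at 0.0516 without BGAL replicate 3 and 0.0361 without L2L3 replicate 3 (range -0.11 to 0.0516). Genes near background, such as PPARGC1A, are limited by signal over background and were not tested.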

Other observations

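Genes in this paragraph and the next were chosen after their values were seen, apart from those the naming rule also names; signals are mean ± SD (n = 3). FOS was at 29.6 ± 2.27 in BGAL, 27.1 ± 4.68 in wt, 475 ± 40.2 in 2x9 and 61.8 ± 45.3 in L2L3. MAFF, a small Maf protein, was at 643 ± 91.1 in BGAL, 478 ± 28.3 in wt, 2026 ± 46.5 in 2x9 and 823 ± 17.5 in L2L3, and the stress factor ATF3 at 594 ± 53.3, 532 ± 10.9, 1634 ± 136 and 512 ± 55.2. EGR1 fell from 1861 ± 147 in BGAL to 349.6 ± 6.83 in wt and 1490.2 ± 77.7 in 2x9, and was at 3344 ± 61.5 in L2L3; in 2x9 against BGAL a dimmer probe set of EGR1 was called higher (log2 0.47), against -0.32 for this one. IER3 went from 9466 ± 659.7 to 1505 ± 58 in wt, 2243 ± 230.4 in 2x9 and 11963 ± 585 in L2L3, where it was called higher (log2 0.34, adjusted p = 0.00904). DUSP6, a phosphatase of ERK kinases, went from 4720.4 ± 133 to 2268 ± 326, 1648 ± 58 and 3899.5 ± 87.2, cyclin D1 (CCND1) from 6428 ± 209 to 2215 ± 158, 1142 ± 114 and 4425 ± 470.3, and MYC from 5037 ± 84.8 to 2420.2 ± 151, 2096 ± 179 and 5142 ± 455 (wt, 2x9 and L2L3). AURKA, a mitotic kinase, rose from 3889.7 ± 286 to 7076 ± 262 in wt and 7254 ± 219.9 in 2x9, and fell to 3007 ± 185 in L2L3 (log2 -0.37, adjusted p = 0.00187).

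ISG15, a ubiquitin-like protein known as interferon-induced, rose from 742 ± 99 in BGAL to 3912 ± 658 in wt and 7935 ± 407 in 2x9, and was at 702 ± 58.8 in L2L3. Of the 21 measured members of the interferon response list, which include ISG15, 2 rose and 3 fell with wt, and 2 rose and 7 fell with 2x9 (camera adjusted p = 0.739 and 0.557). The other member that rose was IRF1, with wt (log2 0.69, adjusted p = 0.000168) and with 2x9 (0.32, adjusted p = 0.0331), and those that fell with wt were IFIT5 (-0.96), MX2 (-0.42) and OAS3 (-0.31). The IFIT5 call was lost without BGAL replicate 1 (log2 -0.93, adjusted p = 0.0678), BGAL replicate 2 (-0.92, 0.0715), wt replicate 1 (-0.96, 0.056) and wt replicate 2 (-0.86, 0.0794). VEGFA, an angiogenic factor, rose from 1975 ± 60.5 to 5205 ± 292 in wt and 4468 ± 358 in 2x9, and was at 1553 ± 365 in L2L3.

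Of the tests below, that of a stronger response of one kind to wt PGC-1 was chosen only after its result was seen. In 2x9 against BGAL, 187 of 2317 genes with 2 or more called probe sets (8.07%) had probe sets called in opposite directions, against 28 of 1830 (1.53%) in wt. With L2L3 in place of BGAL the share was smaller for 2x9, 95 of 1939 (4.90%), against 23 of 1703 (1.35%) for wt. After cyclic loess normalization the share in 2x9 was 8.23% (95% interval 7.15 to 9.43). This argues against an offset between arrays that depends on brightness and that such normalization removes. Among the 187 genes the raised probe set was the dimmer of the pair in 71 (37.97%), so the brighter one rose more often. Both probe sets of the pair changed at least 2-fold in 4 of the 187. Among bright probe sets only, the share in 2x9 was 8.29% (7.10 to 9.61), which argues against dim probe sets. Without probe sets ending in _s_at and _x_at it was 7.68% (6.03 to 9.60), which argues against probe sets shared between related transcripts. The shares in wt were 1.32, 1.06 and 0.885% in the same order. What stays open is a relation to brightness that this normalization does not remove, which was not tested. A change in transcript forms or hybridization to other transcripts also stays open. Neither of these was tested, since probe positions were not used here. No biological explanation was tested.

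The cell cycle list was lower in wt than in 2x9 by a median of -0.54. Among 10000 random lists matched on mean signal, 95% had medians between -0.11 and 0.15, which argues against an offset that depends on brightness. Random lists were drawn without regard to correlation between genes, whereas the members had an estimated correlation of 0.0476. The list's call held with that correlation (camera adjusted p = 0.022). A stronger response of one kind to wt than to 2x9 was not decided by the median in 2x9 against BGAL, -0.0784 (95% bootstrap interval -0.38 to 0.0301) against -0.68 in wt, since members went both ways with 2x9, 8 called higher and 18 lower. Of the 37 members lowered by wt, 18 were also lowered by 2x9 and 5 were raised by it: CCNE2 (log2 -1.79 with wt and 0.49 with 2x9), GINS2, CDT1, BIRC5 and CCNA2, counted and named after their values were seen. For these 5 a response that differs only in size is at odds with the calls. Of the 5, only CCNE2 and CCNA2 were also called so without probe sets ending in _s_at and _x_at and as the mean of all probe sets, where TYMS was added. Without BGAL replicate 1 they were CCNE2, CCNA2 and GINS2, and at a minimum of 2-fold 0 of 10. For the list as a whole, a response of one kind and a different action of the constructs both stay open, as does a difference in the amount of virus or protein, which was not tested.

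The oxidative phosphorylation list was higher in L2L3 than in BGAL by a median of 0.19. Of 10000 matched lists, 95% lay between 0.00891 and 0.12. Matched lists were drawn without regard to correlation between genes, whereas the members had an estimated correlation of 0.113. Their range is thus too narrow to decide whether an offset that depends on brightness is the whole cause. Residual PGC-1 activity of L2L3 is a candidate explanation: members that rose more with wt also rose more with L2L3. The mean correlation across members was 0.314 when no arrays were shared (95% bootstrap interval over members 0.0550 to 0.508). That interval treats members as independent and does not measure the spread between arrays. Both changes were still taken against BGAL arrays, so anything particular to the BGAL group as a whole would also give a positive correlation. The correlation cannot tell that apart from residual activity. Other lists called with wt went both ways in L2L3. Called in the direction of wt were cell cycle (median -0.25, adjusted p = 3.09e-07), the mitochondrial ribosome (0.13, 7.53e-06) and mitochondrial transcription and import (0.097, 0.026). Fatty acid oxidation was called the other way (-0.16, 0.0254), and NR0B2, raised by wt, fell (log2 -0.78). The call of transcription and import was lost without BGAL replicate 3 (adjusted p = 0.116), that of fatty acid oxidation without BGAL replicate 1 (0.0585) or L2L3 replicate 3 (0.0518), and none of these 4 held with an estimated correlation (0.052, 0.266, 0.225 and 0.302). Cytosolic ribosome genes also lay above their matched lists in L2L3 (0.20 against 0.0954 to 0.16). The matched lists were themselves raised, with a middle value of 0.0698 for oxidative phosphorylation and 0.1285 for the cytosolic ribosome. The median over all genes was 0.0218. A wider shift of abundant transcripts thus stays open as a part or the whole of the rise. The oxidative phosphorylation call did not hold with an estimated correlation (adjusted p = 0.116).

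With 3 arrays against 3 there are 10 splits of the 6 arrays, too few for a share under 0.05, and 1 split, the real one, called as many genes as observed in each comparison. Real counts and the highest of other splits were 5085 and 0 for wt vs BGAL and 5977 and 0 for 2x9 vs BGAL. For L2L3 vs BGAL they were 2035 and 1, and for wt vs 2x9 4028 and 0. For wt vs L2L3 they were 5027 and 0, and for 2x9 vs L2L3 5161 and 0. Every other split mixes the 2 real groups, so their difference enters the spread and few calls can follow. The counts of other splits are therefore not a rate of false calls.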
